A study of Homo sapiens with 2 samples.

How the data were processed

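RNA of BxPC3 cells was profiled on a whole human genome CodeLink array with 1 colour, per the labels' protocols: cells were transfected with FuGENE 6, lines were selected with G418 at 800 µg/ml, total RNA was used and targets were stained with Cy5-streptavidin. The labels give 1 array of cells with the empty vector and 1 array of cells with the MSX2 expression vector, and no statement of how many clones or cultures each line came from. The authors deposited 1 value table for both arrays with a normalized intensity for each probe on a linear scale. The median intensity as deposited was 0.972 on the empty vector array and 0.976 on the MSX2 vector array, and the 75th percentile 3.47 and 3.67. The scanner software, background correction and normalization are not given in the sources used here. A value of -9999 marks a spot without a measurement, which was the case for 196 spots of the empty vector array and 206 of the MSX2 vector array. Values at or below 0, which have no log2, made up 5.18% and 5.43% of the measured ones. The number of arrays, 1 per group, limits the precision.

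Gene names came from the platform's annotation table. Of 54359 probes, 23472 carried 1 gene symbol, 905 carried several and 29982 were not named in the table. Only probes with 1 symbol were given a gene, and 23434 of these were found in RefSeq (GRCh38.p14) by Entrez gene number; no symbol had to be renamed. RefSeq also gave each gene's chromosome and the order of neighbours. The build of the array is not given in the sources used here, so no coordinates are reported. No probe was named as a control in the tables used, so none could be left out as one.

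Each array was divided by its median over the 54151 probes measured on both. The floor was the array's median, 1 after scaling, and lower values were set to it. A gene with several probes was represented by the probe with the highest mean log2 value over both arrays, and a gene was detected if that probe was at or above the floor on at least 1 array. Log2 folds are MSX2 vector over empty vector. A gene below the floor on 1 array has a bound, written as at least so many fold. With no replicates no test was run: genes were counted and named by size, the rule being at least 2-fold. The spread between probes was the SD of log2 folds around the gene's mean over genes with several probes above the floor on both arrays.

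The lists, the rule for named genes, the floor, the scaling and all alternatives except those said to be added were set before the data were examined. Named genes were MSX2 and TWIST1, the 15 genes with the largest fold in each direction among those above the floor on both arrays and at or above the 75th percentile on the brighter one, the 5 genes per direction with the highest intensity among those above the floor on 1 array only, and up to 4 members of each list with the largest absolute log2 fold plus its 2 brightest members. Of 33 lists with 813 members, 695 members had a named probe. The median of each list was compared with 10000 random lists of the same size drawn within 20 bins of mean expression. The comparison by chromosome, the blocks of 20 neighbouring genes and the gene families in the closing section were chosen after the values were seen.

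Alternatives were the values as deposited, scaling by the 75th percentile, quantile normalization, loess correction of the log2 fold on mean intensity (span 0.3), floors at the 25th and 75th percentile and none, the median of a gene's probes, the probe brightest on the empty vector array, thresholds of 1.5-fold and 3-fold, list members above the floor on both arrays, and unmatched random lists. A pair of alternatives was added after seeing the data: subtracting each chromosome's median, and leaving out genes of chromosomes 13, 14 and 20. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

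The procedure was tested on simulated data with 18226 genes and 200 changed ones. At a true log2 fold of 2, 50 of 50 genes passed 2-fold (mean estimate 2.03), and at -2, 49 of 50 (mean -1.97). At 0.5, 1 of 50 passed and at -0.5, 0 of 50. No unchanged gene passed, but noise was drawn with the SD between probes, of which 2-fold is 4.49, so this outcome was nearly fixed by the setting. The changed genes were drawn from bright ones above the floor on both arrays. The simulation therefore does not cover bounds or genes near the floor, and gives no rate of false calls for the real arrays. A simulated list with no shift lay at percentile 49.8 and a shifted one at 100.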

Results

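Gene expression was measured in BxPC3 cells, an established human pancreatic cancer cell line, on 2 one-colour oligonucleotide arrays. One array held RNA from cells selected with G418 after transfection with an empty vector, and the other RNA from cells transfected and selected in the same way with a vector carrying MSX2, a homeobox transcription factor. Each group therefore had 1 array, and no p-value, SD between cultures or standard error can be given for any difference between them. The only estimate of error is the spread between different probes of the same gene, whose log2 folds had an SD of 0.22 over 1782 genes (3820 probes), equal to 1.17-fold. It covers probes and not cultures, and a 2-fold difference is 4.49 of these SDs. Among the genes changed at least 2-fold it is a loose guide: 12 had another probe above the floor on both arrays, and in 8 of them all other probes had the same sign. Of 54359 probes, 54151 had a value on both arrays, and 5.18% of values on the empty vector array and 5.43% on the MSX2 array were at or below 0. Intensities are given in units of the array's own median, which also served as the floor: a value below it was set to the floor, and the fold is then a bound. Of 18226 genes with a named probe, 12585 lay at or above the floor on at least 1 array and 11779 on both. Over the 25895 probes at or above the floor on both arrays, log2 intensities had a Pearson correlation of 0.989, taken across probes, which are not independent replicates.

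The first comparison asked whether the transfected cells carried more MSX2 transcript, which checks the labels, and whether TWIST1, the gene that the study's title sets beside MSX2, differed as well. MSX2 (Entrez gene 4488, chromosome 5) had an intensity of 2.07 in the empty vector cells and 10.8 in the MSX2 vector cells, a 5.24-fold rise. TWIST1 (Entrez gene 7291, chromosome 7), a basic helix-loop-helix transcription factor known for its part in epithelial-mesenchymal transition, was at -0.07 in the empty vector cells, below the floor, and at 6.42 in the MSX2 vector cells. It was therefore at least 6.42-fold higher. Each of the 2 genes had 1 named probe, so neither value could be compared with another probe. The probe for MSX2 does not separate transcript of the vector from that of the cells' own gene. Both sizes depend on the floor: with the floor at the 75th percentile of each array the log2 fold of MSX2 is a bound of 1.60 and that of TWIST1 a bound of 0.85, under the 2-fold rule, and with the floor at the 25th percentile that of TWIST1 is a bound of 4.55.

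The second comparison covered all genes. In the MSX2 vector cells 110 genes were at least 2-fold lower and 20 at least 2-fold higher. Among genes above the floor on both arrays, the lower ones were led by KRT14, the keratin of basal epithelial cells, which went from 13.7 to 1.25 (log2 fold -3.46), by the interstitial collagenase MMP1, from 9.32 to 1.27 (-2.88), by KRT4, a keratin of stratified mucosa, from 11.03 to 1.66 (-2.73), and by the interferon-induced gene IFI27, from 37.0 to 6.29 (-2.56). The higher genes, bounds included, were led by LINC00570, LINC02328, TWIST1, NUSAP1, which encodes a spindle protein, and MSX2. Most of the transcriptome lay close together: 96.3% of the genes above the floor on both arrays were within 1.5-fold and 75.4% within 1.2-fold.

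Among the other genes with the largest falls measured on both arrays were GPSM3 (log2 fold -2.48), VAMP5 (-2.28), the protease inhibitors SPINK7 (-2.13) and SPINK4 (-1.80), the aldo-keto reductase AKR1B10, which went from 37.7 to 8.88 (-2.09), the secreted matrix protein CTHRC1 (-2.04), LRIG1, a negative regulator of EGF receptor signalling (-2.03), LYPD2 (-2.03), NREP (-2.01), the secreted protein MSMB (-1.97) and C9orf152 (-1.96). Genes below the floor in the MSX2 vector cells, whose bounds reach the size of the leading folds, included SLC16A10, an amino acid transporter, which was at least 8.51-fold lower, LY96, the partner of Toll-like receptor 4, at least 6.19-fold lower, the secretory protein SCGB1A1, at least 6.01-fold lower, and the collagenase MMP13, at least 5.74-fold lower. The other probe of SLC16A10 was below the floor on both arrays. HMBOX1 was also at least 8.51-fold lower by its brightest probe. Its other probe gave a bound of -0.41 on the log2 scale, the largest it could give, since it stood at 1.33 on the empty vector array.

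Of the genes that rose, NUSAP1 went from 1.89 to 11.98 (6.34-fold), the interferon-induced gene IFIT1 from 2.92 to 7.49 (2.57-fold), SKAP1 from 1.51 to 3.77 (2.49-fold), the helix-loop-helix factor TCF15, on chromosome 20, from 2.04 to 4.98 (2.44-fold), SNCG from 2.23 to 5.39 (2.42-fold), the imprinted non-coding RNA H19 from 95.3 to 200.1 (2.10-fold), the drug efflux transporter ABCG2 from 4.61 to 9.63 (2.09-fold) and NRIP3 from 12.4 to 25.6 (2.07-fold). ABCG2 had another probe, below the floor on the empty vector array, with a log2 bound of 1.06.  LINC02328, on chromosome 14, went from 1.21 to 32.3 (26.7-fold), but its other probe was below the floor on both arrays. LINC00570 was at least 942-fold higher, from -0.01 to 942, and the probe numbered next to it, which has no gene name, had a log2 fold of 9.53. LINC02492, ATXN7 and KIFC3 had bounds of at least 2.34-fold, 2.32-fold and 2.13-fold. Among genes at or above the 75th percentile on the brighter array, the next largest values lay just under 2-fold: IFIT2 at 1.98, SHD at 1.96, NRROS at 1.95, ISM1, on chromosome 20, at 1.90 and ADIRF at 1.87.

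Of these rises, H19, ABCG2 and NRIP3 fall below 2-fold when the arrays are scaled by their 75th percentile, with log2 folds of 0.99, 0.99 and 0.97, as do ABCG2 after loess correction (0.99) and NRIP3 with the median of its probes (0.87), its other measured probe being at 0.69. With the floor at the 75th percentile of each array, which raises the dimmer value, SKAP1, TCF15 and SNCG and, among the lower genes, LRIG1, NREP, C9orf152, LY96, SCGB1A1, MMP13, ADAMTS1, GKN1 and IGFBP2 come under 2-fold, and LINC02492, ATXN7, KIFC3, NKD2, HRK, TNFSF10 and EGLN3 have no fold, both values being under it. At this floor the log2 fold of KRT14 is a bound of -1.87, the log2 fold of KRT4 one of -1.55 and the log2 fold of MMP1 one of -1.31, while the log2 fold of IFI27 stays at -2.56. The counts follow the floor and the threshold: 296 higher and 580 lower with the floor at the 25th percentile, and 175 higher and 353 lower at 1.5-fold.

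**Figure D1:**
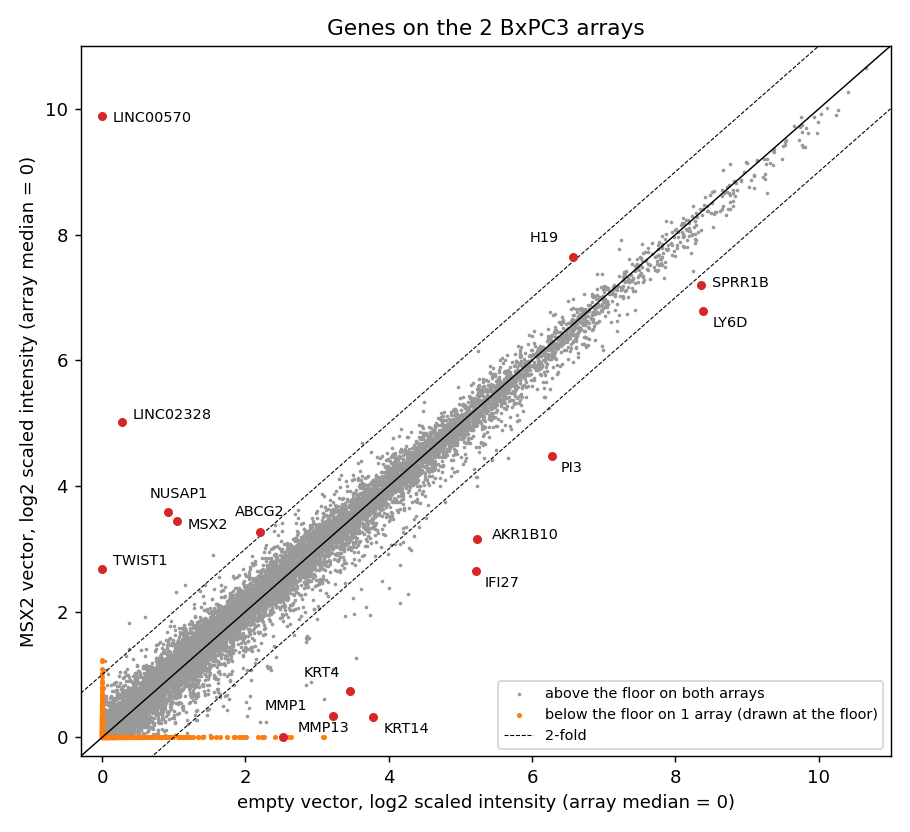
Scaled log2 intensity of each gene on the empty vector array (x axis) against the MSX2 vector array (y axis), with the array median at 0, the solid line at equal intensity and dashed lines at 2-fold. Orange points are below the floor on 1 array and drawn at the floor, and red points are genes picked for labelling. Over all genes drawn, 110 lie at or below the lower dashed line and 20 at or above the upper one.

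The genes were also read through 33 lists fixed before the data were examined. For each list the median log2 fold of its detected members was placed among the medians of 10000 random lists of the same size matched on expression; this percentile describes these 2 arrays and is not a p-value. Besides the list of the study's own pair of genes, 3 lists lay below the middle 95% of random medians and 4 above it. Among those above were the EMT transcription factors, which hold TWIST1 and lay within the range without it.

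The list furthest down was that of squamous and basal genes. Of its 18 detected members, 15 had a log2 fold below 0 and 4 fell at least 2-fold: KRT14 and KRT4, the surface protein LY6D, from 335 to 110.5 (log2 fold -1.60), and the cornified envelope protein SPRR1B, from 328 to 146 (-1.17). The list's median was -0.29, below the medians of all the random lists (percentile 0.0). The 2 brightest members differed less, S100A2 at 976 and 936 and KRT13 at 595 and 482, and so did KRT5 at 318 and 262, a member named after its value was seen. Under all 12 alternatives run on lists this list stayed below that range.

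Ductal and mucin genes were lower as a list as well, with 14 of 21 detected members below 0 and a median of -0.17 (percentile 0.04). The gastric peptide GKN1, from 5.14 to 2.10 (log2 fold -1.29), and the mucin MUC1, from 27.6 to 13.4 (-1.05), fell at least 2-fold, while ANXA10, TFF1 and AGR2 had log2 folds of -0.81, -0.68 and -0.22. With the floor at the 25th percentile the list's median lay at percentile 11.25, within the range of random lists, and without a floor at 9.38.

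Among 23 detected genes of proteases and invasion, 4 fell at least 2-fold: MMP1, MMP13, ADAMTS1, which was at least 4.49-fold lower, and the epithelial metalloprotease MMP7, from 15.02 to 5.58 (log2 fold -1.43). None rose 2-fold, and the inhibitor TIMP1 had a log2 fold of -0.32 and the protease ADAM8 one of 0.04. The median was -0.10 (percentile 1.19) with 13 members below 0 and 10 above, and the list no longer stood apart after quantile normalization (percentile 3.01), after loess correction (2.96), with members above the floor on both arrays only (13.3) or with each chromosome's median subtracted (4.41), an alternative chosen after seeing the data.

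Transcription factors of epithelial-mesenchymal transition had 6 of 14 members detected, of which TWIST1 alone rose past 2-fold. The list holds TWIST1, which the study named, and is not independent evidence of its direction. PRRX1 had a log2 fold of 0.37, SNAI1, on chromosome 20, one of 0.33, SOX9 0.15, TCF3 0.12 and SNAI2 -0.26. The median was 0.24 (percentile 98.41), which became 96.84 without a floor, 88.24 with members above the floor on both arrays only and 91.67 with chromosome medians subtracted. The members above the floor on both arrays are the detected ones other than TWIST1. Target lists of the same transition moved little. No member of the epithelial junctions and keratins (27 detected, median -0.09, percentile 3.41) or of the mesenchymal genes (19 detected, median -0.0006, percentile 32.4) changed 2-fold. CLDN1 had a log2 fold of -0.59, DSP -0.54, JUP -0.38, KRT19 -0.29 and KRT18 0.18, and among mesenchymal genes LOX had -0.72, LOXL2 0.30 and FN1 0.28. CDH1 and VIM were not analysed here.

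Lists of pathways that MSX2 is known to act in lay within the range of the random lists. The ligands and receptors of BMP and TGF-beta were near its lower edge and the WNT list near its upper edge. Among the other MSX and DLX genes, 3 in the list were detected (median 0.17, percentile 86.6), and MSX1 had a log2 fold of 0.46. The ligands and receptors of BMP and TGF-beta (19 detected, median -0.09, percentile 4.02) held FSTL3 at -0.76, BMP2, on chromosome 20, at -0.40 and the activin antagonist FST, from 151 to 242 (0.68). Their response genes (15 detected) had a median of -0.05 (percentile 16.9), with SMAD6 at -0.63 and ID1, on chromosome 20, at -0.29, and osteogenic and tooth genes (7 detected) one of -0.01 (percentile 31.1), with RUNX2 at -0.19. In the WNT list (12 detected) the median of 0.13 (percentile 94.8) and the mean of -0.08 differ in sign, since NKD2, a negative regulator of WNT signalling, was at least 2.25-fold lower and WNT10A had a log2 fold of -0.88. Integrins and laminins (18 detected) had a median of 0.01 (percentile 52.3), with COL4A1, on chromosome 13, at 0.79.

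Lists above the random range shared small shifts. The list named EGFR ligands and receptors (20 detected, 14 above 0, median 0.17, percentile 99.43) also holds genes of other growth factor pathways. The growth factors NRG1, from 8.37 to 14.6 (log2 fold 0.80), and EREG, from 5.67 to 9.72 (0.78), were higher. FGFBP1, from 19.4 to 8.06 (-1.27), and IGFBP2, from 7.28 to 3.04 (-1.26), neither of them an EGFR ligand or receptor, fell at least 2-fold. Genes of the unfolded protein and amino acid stress response (18 detected, 15 above 0, none 2-fold, median 0.16, percentile 99.1) included TRIB3, on chromosome 20, with a log2 fold of 0.57, CHAC1 with 0.54, PSAT1 with 0.43 and DDIT3 with 0.42. Xenobiotic and NRF2 genes (16 detected, 12 above 0) had a median of 0.16 (percentile 99.67), with NQO1 at 0.54 and GCLC at 0.42, but a mean of -0.03, since AKR1B10 fell by 2.09 on the log2 scale. With the floor at the 75th percentile their percentile was 95.44. Immediate early genes (19 detected, 14 above 0, none 2-fold) lay just inside the range, with a median of 0.13 (percentile 97.47), and held FOSL1 at 0.79, DUSP2 at 0.65, PHLDA1 at 0.55 and DUSP5 at 0.48.

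Interferon genes went both ways. Of 29 detected members, 20 were above 0 and the median was 0.11 (percentile 94.96). IFIT1 rose 2.57-fold and HERC5 had a log2 fold of 0.85, whereas IFI27, on chromosome 14, fell by 2.56 on the log2 scale and by 2.41 with its other probe. BST2 had a log2 fold of -0.42 and IFITM3 one of -0.35. In the chemokines and NF-kappaB targets (22 detected, none 2-fold, median 0.03, percentile 53.1) CXCL10 stood at 0.85, LCN2 at -0.81, CXCL8 at -0.69 and NFKBIA, on chromosome 14, at -0.53. Antigen presentation genes (14 detected) had a median of 0.03 (percentile 57.1), with B2M at 0.0006.

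Proliferation genes did not stand apart as a list. None of the 35 detected cell cycle genes changed 2-fold, with 20 above 0 and 15 below, and the median was 0.03 (percentile 67.6). The spindle gene NUSAP1, which rose 6.34-fold, is not in this list. It had 1 named probe, so its rise could not be compared with another probe. Among the members with the largest values, AURKA (log2 fold 0.37), PCNA (0.37) and TPX2 (0.32) lie on chromosome 20, and PLK1 (0.31) on chromosome 16. With chromosome medians subtracted the chromosome 20 members had 0.21, 0.20 and 0.15. Inhibitors of the cell cycle and p53 targets (18 detected) had a median of 0.04 (percentile 65.6), with CDKN1C at -0.90 and CDKN1A at 0.33. Of 18 detected apoptosis regulators (median -0.0034, percentile 30.9), HRK was at least 2.11-fold lower and TNFSF10 fell by 1.08 on the log2 scale. ABC drug transporters (6 detected) had a median of 0.04 (percentile 48.1) with ABCG2 the member that passed 2-fold.

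Metabolic lists were also near the upper edge of the random lists: cholesterol synthesis (17 detected, 14 above 0, median 0.11, percentile 95.1), with LSS at 0.51 and a bound of 0.14 with another probe, and hypoxia and glycolysis (23 detected, median 0.09, percentile 96.0), where VEGFA stood at 0.49, with its other probe at 0.04, and EGLN3, on chromosome 14, was at least 2.10-fold lower, or -0.84 on the log2 scale with chromosome medians subtracted. Stem cell and Notch genes (16 detected) had a median of 0.06 (percentile 77.1), with NES at 0.75, its other probe at 0.20, and NOTCH1 at -0.59. Ribosomal protein genes (39 detected, 30 below 0) had a median of -0.11 (percentile 6.38), with RPS13 at -0.42 and RPS3 at -0.38, its other probe at -0.05; after loess correction the median log2 fold of ribosomal proteins was -0.0065. Histones (11 detected, 9 below 0) had a median of -0.15 (percentile 3.24), against -0.03 over all 30 detected histone genes, a set chosen after the values were seen, of which 19 were below 0. Housekeeping genes (18 detected) had a median of 0.03 (percentile 90.0), with ACTB at 0.39 and EEF1A1 at 0.36.

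Markers of other cells were few and low in change. Of the endothelial markers 5 were detected (median 0.12, percentile 85.5) and of the immune cell markers 5 (median 0.16, percentile 84.0), with no member changed 2-fold. Acinar and endocrine genes (10 detected) had a median of 0.14 (percentile 86.5) and a mean of -0.13. One member, PDX1, on chromosome 13, was at least 3.63-fold lower by its brightest probe, but the other probes of the gene had log2 folds of 0.04 and -0.18, and the list's median turned to -0.14 with the floor at the 25th percentile.

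**Figure D2:**
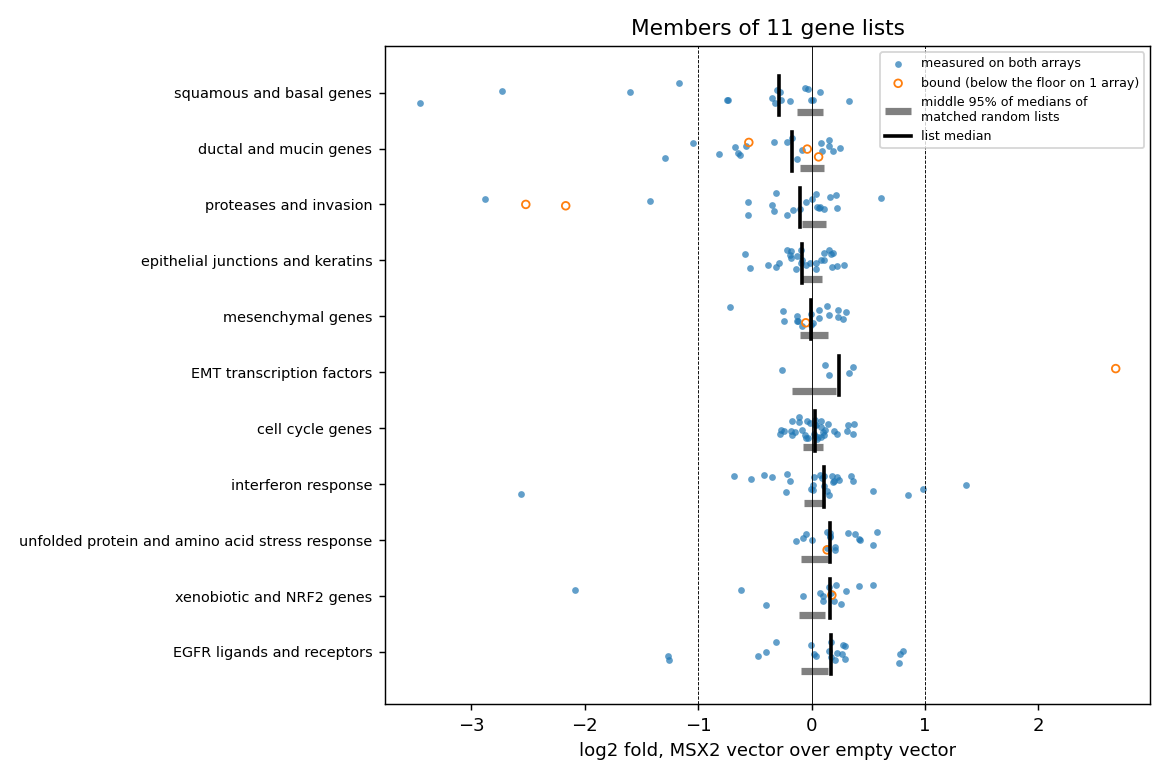
Log2 fold (MSX2 vector over empty vector) of the detected members of 11 lists, 1 point per gene; open circles are bounds, black ticks the list medians and grey bars the middle 95% of medians of matched random lists. The median of squamous and basal genes, -0.29, lies to the left of its bar, and those of EGFR ligands and receptors, 0.17, of the stress response, 0.16, and of xenobiotic genes, 0.16, lie to the right of theirs.

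Ordered by place in the genome, genes of chromosome 14 were lower and those of chromosome 20 higher in the MSX2 vector cells. The order was taken from RefSeq for assembly GRCh38.p14 and used for neighbourhood only, and this comparison was chosen after the values were seen. On chromosome 14, 432 detected genes had a median log2 fold of -0.23, which is 14.7% lower, and 70.6% of them lay below the median of all genes. On chromosome 20, 369 genes had a median of 0.17, which is 12.2% higher, and 74.8% lay above it. All 21 blocks of 20 neighbouring genes on chromosome 14 lay below the median of all genes, and all 18 on chromosome 20 above. On chromosome 13 (242 genes, median -0.04) the first 8 of 12 blocks had medians from -0.32 to -0.07 and the last 4 from 0.01 to 0.15. The medians of the other 20 chromosomes ran from 0.00 to 0.05. Of their 566 blocks, however, 1 near the end of chromosome 4 had a median of -0.43, and the next lowest had -0.17. Chromosome 14, with 432 of the 12585 detected genes, held 10 of the 110 genes at least 2-fold lower, among them IFI27 and EGLN3. That is more than its share of detected genes. Without the genes of chromosomes 13, 14 and 20 there were 94 lower and 17 higher genes.

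**Figure D3:**
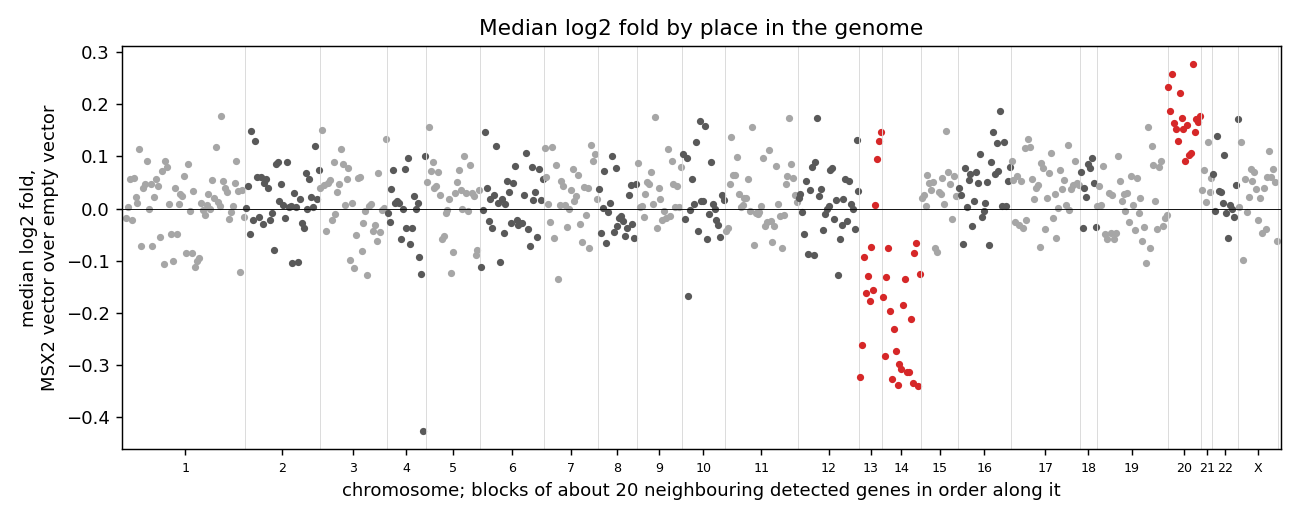
Median log2 fold (MSX2 vector over empty vector, y axis) of blocks of about 20 neighbouring detected genes in order along each chromosome (x axis), with chromosomes 13, 14 and 20 in red. All 21 blocks of chromosome 14 lie below 0, all 18 of chromosome 20 above 0, and the first 8 blocks of chromosome 13 below 0.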

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

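The test on the probe numbered next to LINC00570 was chosen after its result was seen; the other tests were set before their own results were known, but on patterns already noticed in these arrays. Outside the named genes, 15 probes without a gene name were at least 2-fold higher in the MSX2 vector cells, among 12729 such probes detected, and 52 were at least 2-fold lower. The most extreme values among them were 1.06 against 783 (log2 fold 9.53) for the higher and 354 against 1.18 (log2 fold -8.23) for the lower. The higher of these is the probe numbered next to that of LINC00570, discussed below, and not a separate case.

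A few genes had very large folds, with LINC00570 at the highest bound among the named genes. Marks on the array surface would change neighbouring spots together, taking the probe number as a place on the array. Of the genes changed at least 2-fold, 2.31% (3 of 130: LINC00570, TP53I11 and UBE2L6) had a neighbour changed the same way, under the 5% set for marks as a general cause. The share to be met by chance was not computed, and a mark on 1 spot would leave no changed neighbour. The test therefore speaks only to marks over several spots as a cause of most of these folds. The log2 fold of 9.53 in the probe next to LINC00570 is what a mark on that pair of spots would give, so LINC00570 may be such a mark, while a transcript shared by both probes stays untested. Around the MSX2 and TWIST1 probes the highest log2 fold of the 8 surrounding probes of each was 0.19, which argues against a mark covering several spots there. A mark on 1 spot would not show in this test, and each of these genes had 1 named probe.

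Genes of chromosome 14 were lower and those of chromosome 20 higher. A bias that follows brightness is argued against, since after loess correction the medians were -0.259 and 0.132, and so is the place of the probes on the array, since after subtracting the surrounding probes they were -0.265 and 0.122. The shift ran along the whole of chromosome 14, with 70.6% of its genes and 100% of its 21 blocks below the median of all genes, which is consistent with a hypothesis that the 2 selected cell lines differ in copies of chromosome 14 and, by the same pattern, of chromosome 20 and part of chromosome 13. No DNA was measured, and a change in these chromosomes would go with the line and not necessarily with MSX2. An effect of MSX2 on genes along these chromosomes was not tested separately and stays open.

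More genes were lower than higher, 110 against 20. Scaling between the arrays is argued against as the cause, since the ratio of lower to higher genes was 5.9 after quantile normalization and 7.29 after loess correction. The smallest ratio over the 4 other scalings was 5.5, that of the values as deposited. Their array medians are nearly equal, so this setting could hardly differ from the reported one. Genes of chromosome 14 are not enough either: without them 100 genes were lower and 19 higher, a ratio of 5.26. Without a floor the ratio was 1.44, but the SD between probes was also larger there, and noise in both directions would even out the counts. With the floor at the 75th percentile the ratio was 5.125. Whether part of the imbalance lies in which genes stand clear of the floor is therefore not settled. Whether MSX2 or a difference between the selected lines lowered these genes cannot be read from 1 array of each, and no biological explanation was tested.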

How the results depend on the processing

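Subtracting chromosome medians and leaving out chromosomes 13, 14 and 20 were added after seeing the data; the other alternatives were planned. Of 2191 values of 223 named genes other than MSX2 and TWIST1 under the alternatives, those named after their values were seen included, 2113 lay within 1 SD between probes (0.22) of the reported value, 74 moved by more, 59 of them under a floor setting, and 4 reversed. Part of this closeness was fixed in advance and is no evidence of stability. Values as deposited and scaling by the 75th percentile each shift all log2 folds by 1 constant, smaller than this SD. The choice of probe cannot move a gene with 1 probe, and a gene without a fold under an alternative was not counted there. Of 384 list medians, 379 moved by less than 0.5 of the width of the random range, and 5 by more; 37 changed sign, over 14 lists, none of them a list outside the random range as reported. Drawing random lists without matching leaves a list's median as it is, so it could not move any of the 384. Of the lists outside the random range, squamous and basal genes, the stress response and the EGFR list stayed outside under all 12 alternatives, xenobiotic genes under 11, ductal genes under 10, EMT factors, a list that holds TWIST1, under 9 and proteases under 8. The values as deposited and scaling by the 75th percentile are counted among the 12, although they cannot change a percentile. They shift a list and the random lists alike. Signal over background limits these counts, as the floor settings show. The numbers of genes higher and lower became 296 and 580 with the floor at the 25th percentile, 8 and 41 at the 75th, 802 and 1153 without a floor, 175 and 353 at 1.5-fold, and 5 and 40 at 3-fold. The share of lower genes was 84.6% as reported, 66.2% with the floor at the 25th percentile and 59.0% with none. The SD between probes became 0.35 with the floor at the 25th percentile and 0.88 without one. The log2 bound of TWIST1 became 4.55 with the floor at the 25th percentile and 0.85 at the 75th, where MSX2 was a bound of 1.60; without a floor TWIST1 had no value, its intensity in the empty vector cells being below 0. PDX1 reversed to 0.039 with the floor at the 25th percentile and to 0.039 without one, where another of its probes is the brightest, and to 0.053 with the floor at the 75th, which is higher on the MSX2 array and turned KLK13 to 0.071 as well. Acinar and endocrine genes had a median of -0.14 with the floor at the 25th percentile and -0.051 without one; the cause was not tested. The median log2 fold of ribosomal proteins was -0.11 as reported. It was -0.19 when scaled by the 75th percentile, where the constant shift named above applies. It was -0.041 after quantile normalization and -0.0065 after loess correction on mean intensity. The random range for this list, matched on expression, ran from -0.13 to -0.0036, wholly below 0, and held the reported median. Genes of similar brightness were thus lower as well, and no fall particular to ribosomal proteins is shown. Over all detected genes the median log2 fold was 0.02 as reported and -0.05 when scaled by the 75th percentile. The floor from negative control probes was not run, since no such probe is named in the tables used here. No paired analysis was possible because each group has 1 array.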

Other observations

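The gene families and single genes in this part were chosen after their values were seen, as was the subtraction of chromosome medians, and no explanation is offered for them. All 3 detected SPRR genes, whose products build the cornified envelope, were below 0 (median -0.75) here and under the 4 other scalings, with SPRR1A at -0.73 and SPRR3 at -0.75 beside SPRR1B. The elastase inhibitor PI3, on chromosome 20, went from 77.3 to 22.4 (log2 fold -1.79), but it was the only 1 of 7 detected genes of its WAP family to fall 2-fold, the median being -0.07, with SLPI at -0.18 and WFDC2 at 0.08. The antimicrobial peptide DEFB1 went from 50.8 to 21.7 (-1.23), and the kallikrein KLK10 from 11.3 to 4.63 (-1.28), while KLK13 was at least 3.58-fold lower, a bound that turned to 0.071 on the log2 scale with the floor at the 75th percentile. Of 10 detected kallikreins 2 fell 2-fold, and the family's median was 0.03, which turned to -0.05 when scaled by the 75th percentile, to -0.0041 after quantile normalization and to -0.03 after loess correction. S100 genes were mostly slightly lower, 9 of 10 below 0 with a median of -0.15, and between 8 and 10 under the other scalings.

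Troponin genes, known from muscle, were all below 0 (4 of 4, median -0.95), with TNNI2 from 37.7 to 16.1 (log2 fold -1.23) and TNNC1 at least 3.13-fold lower, and this held under the 4 other scalings. Metallothioneins went both ways: MT1H fell by 1.03 on the log2 scale while MT1F and MT1E had 0.63 and 0.58. Beside IFIT1, the interferon-induced chemokine CXCL11 was 2.04-fold higher, under 2-fold when scaled by the 75th percentile (log2 fold 0.95) or after loess correction (0.98). IFI27L2, on chromosome 14 like IFI27, fell by 1.02, but stood at -0.82 with the median of its probes and at -0.79 with chromosome medians subtracted. UBE2L6, also interferon-induced, fell by 1.61, but its probe is numbered next to that of TP53I11, which fell by 1.32 and stood at -0.75 with the median of its probes. PHLDA1, an immediate early gene, had log2 folds of 0.70 and 1.00 with its other probes, and FOSL1 0.68 with its other probe, in the same direction as their brightest probes.

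Spots without a value lay together on the arrays: of 208 such spots, nearly all without a value on both arrays (196 on the empty vector array and 206 on the other), 49 had a neighbour without a value, against a median of 6 and at most 18 in 1000 random draws. Of the 566 blocks of neighbouring genes outside chromosomes 13, 14 and 20, the lowest had a median log2 fold of -0.43 and the next lowest -0.17. It lies near the end of chromosome 4, and HPGD, which degrades prostaglandins, had -1.26 there by its brightest probe, with almost no difference by its other probe, CDKN2AIP -0.96, TRAPPC11 -0.90 and WWC2 -0.87, while TENM3 had 0.47.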
